A study of Mus musculus with 39 samples.

How the data were processed

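Gene expression was measured in mouse testis on Affymetrix GeneChip arrays with biotin-labelled cDNA, in 39 animals of 8 groups. Wild-type mice (WT) and 3 lines in which a Cre transgene was combined with floxed Prkar1a were sampled at 2 weeks and at 2 months. The lines carried Sf1:Cre (prKO), Amh:Cre (srKO) or Cyp11a1:Cre (lrKO). The deposited table holds log2 intensities per probe set that the authors normalized with RMA. The version, settings and software of RMA, and the genome build and annotation behind the array, are not given in the sources used here, so no genomic coordinates are printed. The label on RNA extraction names the adrenal gland, whereas all other labels name whole testis. The values lay between 2.54 and 13.62, no pair of arrays had identical values, and all 39 columns were used. Arrays give no read depth, so the number of arrays limits the precision.

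The table held 41345 probe sets. The annotation gave 1 gene symbol to 23521 of them, several symbols to 1814 and listed none for 16010, and only the first class entered the gene tests. Symbols were checked by Entrez identifier against a reference table of mouse genes, which held 23328 of these probe sets and changed 0 symbols. For 1082 of 22180 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used. A gene was tested when the mean of at least 1 of the 8 groups exceeded the 25th percentile of all values (4.62), which left 19007 genes. No further normalization was applied.

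Groups were taken from the sample titles. At each age 1 linear model with the 4 genotypes was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and 1 model with all 8 groups was fitted for comparisons between ages. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05; the number of called genes that also changed at least 2-fold is given beside each count. Each line was compared with WT, and the lines with each other. A non-additivity contrast subtracted the srKO and lrKO changes from the prKO change on the log2 scale. The last contrasts compared WT between ages and each line's change between ages. Values after ± are standard errors of the log2 difference, and folds are 2 to the power of that difference.

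There were 24 gene lists holding 328 genes, of which 282 were tested: protein kinase A (PKA) subunits and inhibitors, cAMP and CREB target genes, Sertoli cell markers, steroidogenic enzymes and carriers, Leydig cell identity and maturation, cholesterol synthesis and uptake, adrenal cortex genes, granulosa cell and ovarian genes, WNT pathway targets and feedback genes, spermatogonia, meiotic prophase, spermatids, peritubular myoid and smooth muscle, macrophages and antigen presentation, lymphocytes and mast cells, endothelium, extracellular matrix, bone and mineralisation, cell cycle, interferon response, epididymis, adipose tissue, red blood cells, and reference genes. The red blood cell list had 1 tested member and was not tested as a set. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The test fry was run beside it; it asks whether a list moves 1 way on balance and does not compare the list with other genes. Members past the threshold are counted over all genes tested and adjusted over the list alone. Members of a list without a probe set of 1 symbol were not analysed here.

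Genes were named by a fixed rule. It took Prkar1a, the 6 largest rises and 6 largest falls among the genes past the threshold in each comparison with WT (5 and 5 in other comparisons), and up to 4 members of each list with the largest absolute log2 change. Model and clone names, small nucleolar and micro RNA genes, and olfactory and vomeronasal receptors were passed over. The groups, comparisons, lists, naming rule and all alternatives except those said to be added later were fixed before the data were examined.

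Other settings tried were no filter on dim probe sets, a stricter filter at the 50th percentile (5.94, 14854 genes), the average of a gene's probe sets, quantile normalization again, centring of each array on its median, array weights, eBayes with trend and robust settings, a fit of only the groups compared, a fit of all 8 groups, the replicate number as a block, leaving out each array, and fry or an estimated correlation for lists. After the WT arrays were seen to separate by replicate number, WT replicates 1 to 4 and 5 to 8 were each used alone, and crossed assignments of these sets were used for differences between lines. A fit without the arrays high in Adam7 was also added. Overlaps between lines were set beside 100 simulations with unchanged groups against the same WT arrays, beside the expectation for independent lists (the product of both counts divided by the genes tested), and beside a split of the WT arrays. Group labels were regrouped in 100 random splits, or in all splits where fewer exist.

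The procedure was tested on simulated data with 200 of 19007 genes changed, which does not bound false calls in real arrays. With 4 against 8 arrays it recovered 73.1% of 1.41-fold, 95.5% of 2-fold and 98.5% of 4-fold changes, and 2.2% of its calls were unchanged genes. With 3 against 8 arrays the shares were 67.2%, 94.0%, 100% and 4.9%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.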

Results

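RNA of whole testis was profiled in 39 mice, with 8 WT, 4 prKO, 4 srKO and 4 lrKO animals at 2 weeks and 8 WT, 3 prKO, 4 srKO and 4 lrKO animals at 2 months. Prkar1a encodes the type 1 alpha regulatory subunit that holds PKA, the main cAMP-dependent kinase, inactive. Sf1:Cre is active in the common somatic precursors of the gonad and the adrenal cortex, Amh:Cre in Sertoli cells, which nurse the germ cells, and Cyp11a1:Cre in steroid-producing cells, which in the testis are the Leydig cells. RNA of whole testis does not tell a change within cells from a change in the share of cell types. The median log2 intensity of single arrays lay between 5.96 and 6.02 at 2 weeks and between 5.81 and 5.96 at 2 months. The lowest correlation between arrays of a group, taken across genes, which are not independent replicates, was 0.951 in WT at 2 weeks and 0.949 in prKO at 2 months, and at least 0.975 in the other groups. WT replicates 1 to 4 and 5 to 8 differed in 221 genes at 2 weeks and 407 at 2 months, a comparison chosen after the data were seen.

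Prkar1a (probe set 17257874) was lower in all 4 prKO arrays at 2 weeks (8.04 to 8.33) than in any of the 8 WT arrays (8.84 to 9.14), a fall of 1.71-fold (log2 change -0.78 ± 0.07, adjusted p = 4.5e-07). It also fell in srKO at 2 weeks, by 1.4-fold (-0.48 ± 0.07, adjusted p = 0.0022), again in 4 of 4 arrays beyond all WT. In the arrays labelled lrKO it did not pass the test at either age (0.05 ± 0.07, adjusted p = 0.84 at 2 weeks; 0.04 ± 0.08, adjusted p = 0.94 at 2 months). At 2 months it fell in prKO (-0.30 ± 0.09, adjusted p = 0.0078), with 1 of 3 arrays below all WT. WT replicates 1 to 4 all lay below 5 to 8 in Prkar1a, at most 8.95 against at least 8.99 at 2 weeks and 8.81 against 8.95 at 2 months. In the arrays labelled srKO at 2 months it rose (0.24 ± 0.08, adjusted p = 0.03), with 3 of 4 arrays above all WT. The probe set spans the transcript, the position of the deleted part in it is not known here, and cells without the Cre also contribute, so these values do not measure recombination. The fall in prKO at 2 months was not called without prKO replicate 3 (-0.20, adjusted p = 0.097), with the replicate block (-0.173, adjusted p = 0.19) or against WT replicates 1 to 4 alone (-0.175, adjusted p = 0.079), but was against 5 to 8 alone. In lrKO at 2 months it was called against neither set, with 4 of 4 arrays (8.86 to 8.90) between them. The rise in the arrays labelled srKO was not called after centring (0.205, adjusted p = 0.091), against WT replicates 5 to 8 alone (0.12, adjusted p = 0.29), or without WT replicate 3 (adjusted p = 0.052), WT replicate 4 (adjusted p = 0.05), or srKO replicate 2 (adjusted p = 0.077), 3 (adjusted p = 0.096) or 4 (adjusted p = 0.06).

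**Figure D1:**
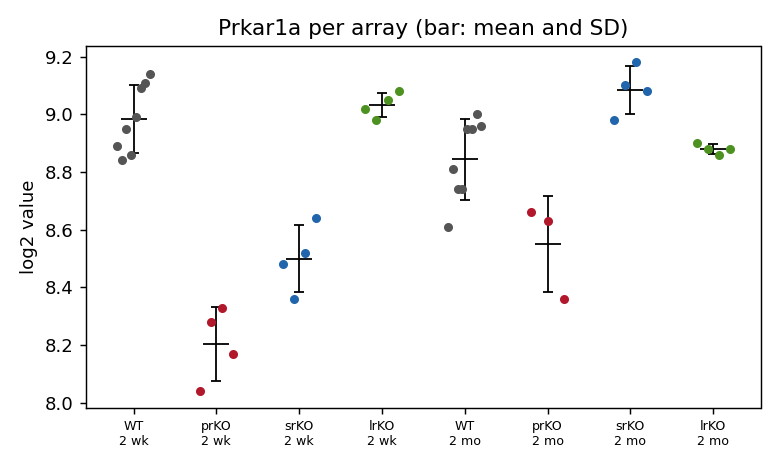
Prkar1a log2 intensity (vertical axis) in each array, by group (horizontal axis); points are arrays, bars the mean and SD of the group. The prKO arrays at 2 weeks (8.04 to 8.33) and srKO arrays at 2 weeks (8.36 to 8.64) lie below all 8 WT arrays (8.84 to 9.14), whereas the lrKO arrays (8.98 to 9.08) lie among them.

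In prKO at 2 weeks steroid synthesis genes were among the 6 largest rises against WT. Cyp21a1, the 21-hydroxylase of the adrenal cortex, rose at least 18.6-fold (4.22 ± 0.23, adjusted p = 4.2e-10). Its WT arrays (4.26 to 4.61) lay below the filter value of 4.62, and folds against such background signal are given as at least. Star, which carries cholesterol into mitochondria, rose 7.89-fold (2.98 ± 0.23), and Cyp11a1, which makes the first step of steroid synthesis from cholesterol, rose 7.6-fold (2.93 ± 0.18). The cAMP phosphodiesterase Pde7b rose 8.21-fold (3.04 ± 0.20), and the cystine transporter gene Slc7a11 (2.87 ± 0.18) and the complement gene C7 (3.01 ± 0.31) were also among the largest rises. Each of these was above all 8 WT arrays in 4 of 4 prKO arrays. The largest falls were in Sel1l3 (-1.51 ± 0.35, adjusted p = 0.0085), the cardiac troponin gene Tnni3 (-1.30 ± 0.17, adjusted p = 3e-05) and Plbd1 (-1.14 ± 0.15, adjusted p = 3.7e-05), each below all WT in 4 of 4 arrays.

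By list in prKO at 2 weeks, 7 of 9 steroidogenic enzymes and carriers rose (8 adjusted over the list alone). Among them were Cyp17a1 (1.86 ± 0.34, adjusted p = 0.0012) and Hsd3b1 (1.65 ± 0.13), and the list call (adjusted p = 2.7e-13) remained with an estimated correlation (adjusted p = 0.012). Of 15 cholesterol genes 14 rose (14 adjusted over the list alone). Among them were Cyp51 (1.47) and Nsdhl (1.10). The list had adjusted p = 8.3e-16 and 0.045 with an estimated correlation. Of 5 adrenal cortex genes 2 rose (3 adjusted over the list alone), Cyp21a1 and the melanocortin receptor partner Mrap (5.09-fold, 2.35 ± 0.20), with list adjusted p = 0.00012, and 0.014 with an estimated correlation. The mean (1.37) exceeded the median (0.23), and Cyp11b1, a glucocorticoid enzyme, was at 0.23 (adjusted p = 0.11), although it was called without prKO replicate 1 (0.34, adjusted p = 0.018). Of 21 cAMP and CREB target genes 7 rose and 0 fell (8 rose adjusted over the list alone). Among them were the nuclear receptor genes Nr4a1 (2.14-fold, 1.10 ± 0.13) and Nr4a3 (0.99). The list had adjusted p = 3.4e-05, and 0.018 with an estimated correlation. Of 8 PKA genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with Prkar2b, another PKA regulatory subunit, up 1.79-fold (0.84 ± 0.12). The list was not called (adjusted p = 0.22). Of 8 Leydig cell genes 4 rose (4 adjusted over the list alone). Among them were the lineage regulator Nr5a1 (0.91 ± 0.07), which is also the driver gene of this line's Sf1:Cre, and the estrogen sulfotransferase Sult1e1 (1.07). The list had adjusted p = 0.00078, but 0.21 with an estimated correlation.

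Matrix, endothelial, macrophage and bone lists were called higher in prKO at 2 weeks at the preset correlation, but not with an estimated one. In the matrix, endothelial, macrophage, Leydig and cAMP scores 2 of 4 prKO arrays lay within the WT range. Of 21 matrix genes 18 rose (19 adjusted over the list alone). Among them were the gelatinase gene Mmp2 (3.13-fold, 1.65 ± 0.19) and the crosslinking enzyme Lox (1.61). The matrix list had adjusted p = 8.4e-19, but 0.062 with an estimated correlation, and WT replicate 4 stood above the other WT arrays in it (0.75, nearest 0.06). Of 9 endothelial genes 5 rose (5 adjusted over the list alone; adjusted p = 3.4e-05, and 0.11 with an estimated correlation). An example was Pecam1 (0.73, not called with the replicate block at 0.61, adjusted p = 0.05). Of 17 macrophage genes 5 rose (5 adjusted over the list alone; adjusted p = 0.001, and 0.24 with an estimated correlation). Examples were Cd163 (0.92) and Mrc1 (0.85). Of 7 bone genes 3 rose (3 adjusted over the list alone; adjusted p = 0.031, and 0.21 with an estimated correlation), including Alpl (1.29) and Omd (0.95), with a median of 0.04. This list was not called against WT replicates 5 to 8 alone (adjusted p = 0.15) or with only the groups compared (adjusted p = 0.054). In the same arrays 4 of 22 Sertoli cell genes rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.82): the inhibin subunit gene Inha was at 0.53 ± 0.09 and the follicle-stimulating hormone receptor gene Fshr at -0.69 ± 0.12.

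Of 22 meiotic prophase genes in prKO at 2 weeks 1 fell and 0 rose (1 fell adjusted over the list alone). The list was called lower (mean -0.35, adjusted p = 0.0021), but not with an estimated correlation (adjusted p = 0.48), with the replicate block (adjusted p = 0.27) or against WT replicates 1 to 4 alone (adjusted p = 0.24). Its largest members, Piwil1 (-0.98, adjusted p = 0.42) and Spo11 (-0.85, adjusted p = 0.054), were not called, although Spo11 passed without WT replicate 1 (adjusted p = 0.02), WT replicate 4 (adjusted p = 0.014) or prKO replicate 3 (adjusted p = 0.041). Spo11 also passed with the stricter filter, either rescaling, array weights (adjusted p = 0.0083), all 8 groups (adjusted p = 0.0066) or WT replicates 5 to 8 alone (-1.27, adjusted p = 0.0018). The exact permutation test of the mean of this list per array gave p = 0.13 (two-sided), with 3 of 4 prKO arrays within the WT range. The other lists were not called. They gave 1 of 18 spermatogonial genes higher (adjusted p = 0.073), 0 of 19 spermatid genes called (adjusted p = 0.55), 0 of 7 myoid genes (adjusted p = 0.78), 0 of 12 cell cycle genes (adjusted p = 0.55) and 0 of 4 epididymal genes (adjusted p = 0.55). They also gave 1 of 15 granulosa genes higher (Rspo1, 0.72, adjusted p = 0.55 for the list), 3 of 15 WNT genes higher (adjusted p = 0.4), 1 of 6 mast cell and lymphocyte genes higher (adjusted p = 0.2), 1 of 7 interferon genes higher (adjusted p = 0.073), 1 of 6 adipose genes higher (adjusted p = 0.32), and 1 reference gene higher and 1 lower of 8 (adjusted p = 0.84).

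In all, 1994 genes were called in prKO at 2 weeks, 1501 higher and 493 lower, and 165 of them changed at least 2-fold (155 higher, 10 lower). After centring the calls were 1306 higher and 788 lower. The count was 830 against WT replicates 1 to 4 alone, 4361 against WT replicates 5 to 8 alone, 598 with the replicate block, 3834 with array weights and 1241 with only the groups compared. It was 1298 without prKO replicate 1 and 3119 without WT replicate 4.

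**Figure D2:**
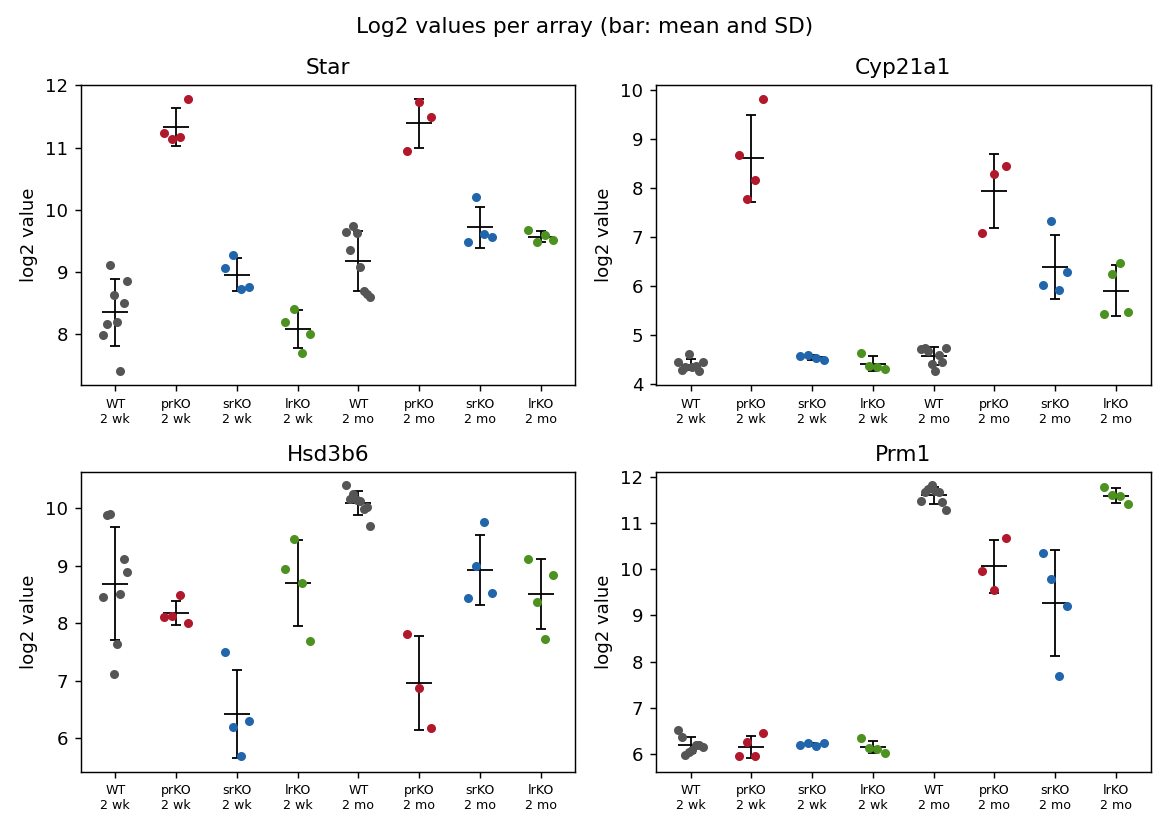
Log2 intensity (vertical axes) of Star, Cyp21a1, Hsd3b6 and Prm1 in each array, by group (horizontal axes); points are arrays, bars the mean and SD of the group. Star was 7.89-fold and Cyp21a1 at least 18.6-fold higher in prKO than in WT at 2 weeks, and Prm1 was lower in prKO and srKO than in WT at 2 months.

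In srKO at 2 weeks phosphodiesterase genes led the rises: Pde7b rose 3.67-fold (1.87 ± 0.20, adjusted p = 4.9e-05) and Pde10a 2.43-fold (1.28 ± 0.14), each above all 8 WT arrays in 4 of 4 srKO arrays. Prkar2b rose 1.72-fold (0.78 ± 0.12, adjusted p = 0.0023). The lipoprotein receptor gene Scarb1 (0.48 ± 0.07, adjusted p = 0.0023) and the last enzyme of cholesterol synthesis, Dhcr7 (0.50 ± 0.08, adjusted p = 0.0061), rose slightly. Star (0.60, adjusted p = 0.24) and Cyp21a1 (0.16, adjusted p = 0.8), which were among the 6 largest rises in prKO, did not pass the test. The lines are compared below. The ion channel gene Kcnma1 rose (0.82 ± 0.11, adjusted p = 0.0012), but its value was -0.53 (adjusted p = 0.54) with the average of its probe sets.

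By list in srKO at 2 weeks, 2 of 21 cAMP and CREB target genes rose (3 adjusted over the list alone), Nr4a1 and the CREB-regulated kinase gene Sik1, with list adjusted p = 0.012, but 0.49 with an estimated correlation. Nr4a1 (0.68, adjusted p = 0.017) was not called without srKO replicate 1 (adjusted p = 0.093), 2 (adjusted p = 0.057) or 3 (adjusted p = 0.055), and Sik1 (0.62, adjusted p = 0.017) not without srKO replicate 1 (adjusted p = 0.074), 2 (adjusted p = 0.088) or 3 (adjusted p = 0.05). Nr4a1, Sik1, Inha, Gata1 and Hsd3b6 were also not called against WT replicates 5 to 8 alone (adjusted p = 0.094, 0.09, 0.12, 0.088 and 0.087). With only the groups compared Nr4a1, Sik1, Inha and Hsd3b6 were not called (adjusted p = 0.088, 0.1, 0.13 and 0.097). Of 22 Sertoli cell genes 2 rose and 0 fell (6 and 1 adjusted over the list alone), Inha (0.43) and Gata1 (0.35), with list adjusted p = 0.0037, but 0.91 with an estimated correlation and 0.21 against WT replicates 1 to 4 alone. Inha was not called without WT replicate 2 (adjusted p = 0.054), srKO replicate 1 (adjusted p = 0.14) or 2 (adjusted p = 0.12), and Gata1 was not called without srKO replicate 1 (adjusted p = 0.093) or 2 (adjusted p = 0.085). The macrophage list was called lower (mean -0.24, adjusted p = 0.00022; adjusted p = 0.49 with an estimated correlation) with 0 of 17 members called (0 adjusted over the list alone). Of 8 PKA genes 1 rose and 1 fell (adjusted p = 0.73), of 9 steroidogenic genes 1 rose and 1 fell (adjusted p = 0.4, with the mean at -0.04 and the median at 0.18), and of 15 cholesterol genes 1 rose (adjusted p = 0.6). The steroidogenic gene that fell was Hsd3b6 (4.83-fold, -2.27 ± 0.45, adjusted p = 0.02), which was not called without srKO replicate 2 (adjusted p = 0.095) or 3 (adjusted p = 0.096). Of 18 spermatogonial genes 2 rose (4 adjusted over the list alone; adjusted p = 0.35), and 1 of 21 matrix genes rose (adjusted p = 0.73). No member was called in the Leydig, adrenal, granulosa, WNT, meiotic (mean -0.29, adjusted p = 0.34), spermatid, myoid, lymphocyte, endothelial, bone, cell cycle, interferon, epididymal, adipose or reference lists, whose lowest adjusted p was 0.34.

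In all, 166 genes were called in srKO at 2 weeks, 149 higher and 17 lower, and 4 of them changed at least 2-fold (2 higher, 2 lower): Pde7b, Pde10a, Hsd3b6 and a microRNA gene that the naming rule passes over. The count was 1040 against WT replicates 1 to 4 alone, 63 against WT replicates 5 to 8 alone, 595 with the replicate block, 276 after centring, 2234 with array weights, 265 with all 8 groups and 39 with only the groups compared. Of 100 splits of these arrays into groups of the same sizes, 5 called at least as many genes, the real split included. The count was 84, 103, 318, 91 and 94 without WT replicate 2, 3, 5, 6 and 7, and 33, 38, 57 and 362 without srKO replicate 1, 2, 3 and 4.

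In the arrays labelled lrKO at 2 weeks the semaphorin gene Sema7a, which codes for a membrane-anchored signal protein, rose 2.14-fold (1.10 ± 0.08, adjusted p = 1.5e-07) in 4 of 4 arrays above all WT, and stayed called under every alternative run; it lies 1 position from Cyp11a1, the gene of this line's Cre driver, in the order of protein-coding genes. Ahcy, which clears S-adenosylhomocysteine, rose (0.89 ± 0.11, adjusted p = 0.00055), but not with the average of its probe sets (0.24, adjusted p = 0.49). The Sertoli cell cystatin gene Cst9 fell 3.19-fold (-1.67 ± 0.23, adjusted p = 0.0027), which was not called with only the groups compared (adjusted p = 0.056). Steroidogenic genes did not pass the test: Star was at -0.28 (adjusted p = 0.72), Cyp17a1 at -1.06 (adjusted p = 0.35) and Hsd3b1 at -0.46 (adjusted p = 0.26).

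By list in the arrays labelled lrKO at 2 weeks, 0 of 9 steroidogenic genes were called (2 fell adjusted over the list alone; adjusted p = 0.21), 0 of 15 cholesterol genes (adjusted p = 0.051), and 1 rose and 1 fell of 22 Sertoli cell genes (adjusted p = 0.082). The PKA (adjusted p = 0.029), granulosa (adjusted p = 0.032), WNT (adjusted p = 0.032) and spermatogonial (adjusted p = 0.032) lists were called lower and the meiotic list higher (mean 0.22, adjusted p = 0.032), each with 0 members called. With an estimated correlation these 5 lists gave adjusted p of 0.39, 0.69, 0.69, 0.39 and 0.69. The meiotic list turned lower against WT replicates 5 to 8 alone (adjusted p = 0.57). Of 19 spermatid genes 1 rose, Tssk1 (0.60, adjusted p = 0.0085; not called without lrKO replicate 3, adjusted p = 0.079; adjusted p = 0.62 for the list). The remaining lists had 0 members called and adjusted p of 0.22 or more.

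In all, 19 genes were called in the arrays labelled lrKO at 2 weeks, 7 higher and 12 lower, and 3 of them changed at least 2-fold (1 higher, 2 lower). The count was 1026 against WT replicates 1 to 4 alone, 583 with the replicate block, 37 with array weights, 38 with all 8 groups and 3 with only the groups compared. Another split of these arrays called 1653 genes. The count was 8 without WT replicate 3, and 7, 7, 5 and 9 without lrKO replicate 1, 2, 3 and 4.

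In prKO at 2 months the largest rises against WT were of mixed kinds. Dpt, a dermal matrix protein gene, rose 25.1-fold (4.65 ± 0.30), the acute-phase gene Serpina3n 24.3-fold (4.60 ± 0.39) and Mmp2 16.8-fold (4.07 ± 0.34), each in 3 of 3 arrays above all 8 WT. Prnd, which codes for the prion-like protein doppel of the testis, fell 15.7-fold (-3.97 ± 0.15, adjusted p = 3e-12), and Hsd3b6, an enzyme of adult Leydig cells, fell 8.87-fold (-3.15 ± 0.31). Star remained higher than in WT, by 4.66-fold (2.22 ± 0.24), as did Cyp11a1 (3.7-fold, 1.89 ± 0.14), Mrap (6.01-fold, 2.59 ± 0.19) and Cyp21a1 (at least 10.3-fold, 3.37 ± 0.29). The spermatid genes Prm1, a protamine gene (2.89-fold, -1.53 ± 0.34, adjusted p = 0.001), and Tssk6, a kinase gene (-2.05), fell. Probe sets of closely related genes, such as Hsd3b1 and Hsd3b6, the Klk1b and Serpina3 families, Hmgb1-rs17 and Rpl10l, cannot be assumed to read 1 gene each. Centring shifted every log2 change of this comparison by -0.12 and of prKO against lrKO at 2 months by -0.13.

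By list in prKO at 2 months, 8 of 8 Leydig genes rose (8 adjusted over the list alone). Among them were Sult1e1 (1.78) and the Cre driver gene Nr5a1 (1.35). The Leydig list had adjusted p = 1e-04, but 0.13 with an estimated correlation. Of 9 steroidogenic genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0087, and 0.28 with an estimated correlation). Of 15 cholesterol genes 13 rose (13 adjusted over the list alone; adjusted p = 5.9e-07, and 0.13 with an estimated correlation). Examples were Hsd17b7 (1.96) and Msmo1 (1.65). Of 5 adrenal genes 4 rose (4 adjusted over the list alone; adjusted p = 0.0016, and 0.13 with an estimated correlation), Cyp11b1 (2.00 ± 0.30) among them. Of 22 Sertoli cell genes 14 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.0016, and 0.38 with an estimated correlation). Among them were Kitl (1.60) and Inha (1.39), but the score of prKO replicate 1 (0.082; 0.603 and 0.625 in 2 and 3) lay within WT (up to 0.134). Of 15 granulosa genes 8 rose and 1 fell (10 and 2 adjusted over the list alone; 6 and 2 after centring). Wnt4 (1.48) was among those higher. The list was called (adjusted p = 0.028), but not with an estimated correlation (adjusted p = 0.28) or the stricter filter (adjusted p = 0.081). Of 19 spermatid genes 18 fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 9e-08, and 0.13 with an estimated correlation). Of 22 meiotic genes 16 fell (18 adjusted over the list alone; 21 after centring and 13 after quantile normalization). Among them were Tex11 (-1.19) and Dmc1 (-0.85). The list had adjusted p = 9.6e-06, but 0.13 with an estimated correlation. Of 18 spermatogonial genes 4 rose and 8 fell (4 and 9 adjusted over the list alone; 3 and 10 after centring; adjusted p = 0.19). Zbtb16, a gene of undifferentiated spermatogonia, was at 0.98.

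PKA genes split in prKO at 2 months: of 8, 3 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.68), with Prkar2b up 4.57-fold (2.19 ± 0.12) and Prkar2a at -1.65 ± 0.26. Of 21 cAMP and CREB target genes 8 rose and 4 fell (8 and 4 adjusted over the list alone; 6 and 5 after centring; adjusted p = 0.24), with Rgs2 at 1.93 and Nr4a1 at -0.63. Of 21 matrix genes 21 rose (21 adjusted over the list alone; adjusted p = 5.9e-12, and 0.13 with an estimated correlation). Among them were the protease inhibitor gene Timp1 (13.1-fold, 3.71) and Lum (2.72). Of 9 endothelial genes 9 rose (9 adjusted over the list alone; adjusted p = 0.00012, and 0.19 with an estimated correlation). Emcn (1.77) was among them. Of 17 macrophage genes 13 rose (13 adjusted over the list alone; adjusted p = 0.00023, and 0.25 with an estimated correlation). Among them were Lyz2 (2.42) and Cd163 (1.52). Of 6 adipose genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0087, and 0.31 with an estimated correlation). Among them was Fabp4 (9.02-fold, 3.17 ± 0.71), which was above all WT in 2 of 3 arrays (10.25 in replicate 1 and 8.48 in replicate 3). The epididymal list gave 0 of 4 called (adjusted p = 0.81), but its member Adam7 was at 11.7 in prKO replicate 1 against a mean of 4.36 in the other prKO arrays, and its change (2.06 ± 1.02, adjusted p = 0.1) was called without prKO replicate 2 (adjusted p = 0.016) or 3 (adjusted p = 0.026). Without the arrays high in Adam7 the adipose list was not called (adjusted p = 0.11), nor was the fall of the spermatogonial gene Kit (-0.69 with all arrays, adjusted p = 0.0022; -0.33 without them, adjusted p = 0.077). Of 8 reference genes 5 rose (5 adjusted over the list alone; adjusted p = 0.022, and 0.13 with an estimated correlation). Among them were Pgk1 (1.26) and Gapdh (0.90). Of 12 cell cycle genes 6 fell (7 adjusted over the list alone; 8 after centring; adjusted p = 0.031, and 0.25 with an estimated correlation). An example was Bub1 (-0.48), and this list was not called with the stricter filter (adjusted p = 0.055), after quantile normalization (adjusted p = 0.087) or against WT replicates 5 to 8 alone (adjusted p = 0.072). Not called were the WNT (6 of 15 higher and 1 lower, adjusted p = 0.06; Sfrp1, a WNT antagonist, at 2.36), myoid (5 of 7 higher and 1 lower, adjusted p = 0.068), interferon (2 of 7 higher, adjusted p = 0.22), bone (1 of 7 higher, Alpl, adjusted p = 0.6) and lymphocyte and mast cell lists (2 of 6 higher and 1 lower, adjusted p = 0.9, with the mean at 0.09 and the median at -0.08).

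In prKO at 2 months 9206 genes were called, 4948 higher and 4258 lower, and 1589 of them changed at least 2-fold (928 higher, 661 lower). After centring, 3711 were called higher and 6062 lower. No alternative moved the count by more than 1.5 times. The small RNA score was 0.26, 0.48 and 0.70 in the 3 prKO arrays, above all 8 WT (-0.22 to 0.16).

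**Figure D3:**
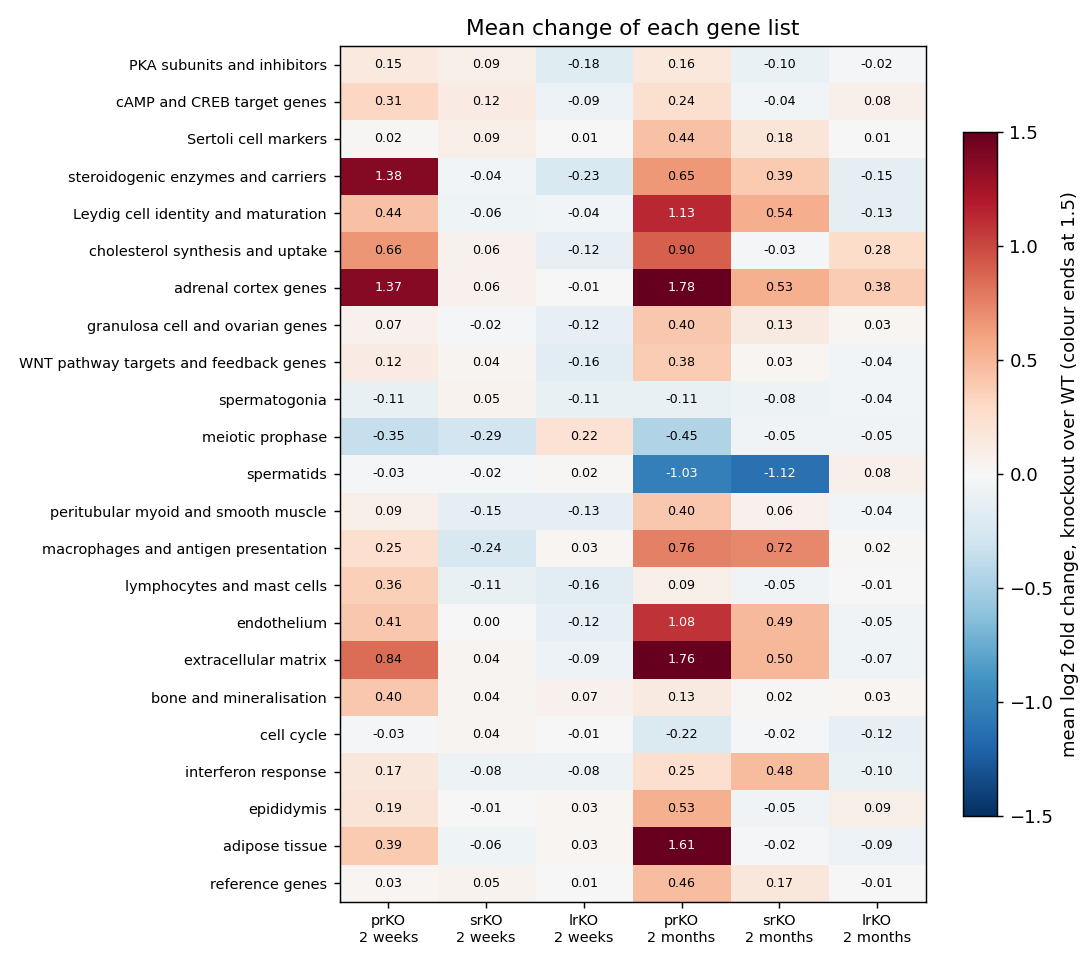
Mean log2 change against WT (colour scale) of the tested members of 23 gene lists (vertical axis) in each line and age (horizontal axis). Matrix genes averaged 0.84 in prKO at 2 weeks and 1.76 at 2 months, and spermatid genes -1.03 in prKO and -1.12 in srKO at 2 months.

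In the arrays labelled srKO at 2 months Serpina3n rose 8.79-fold (3.14 ± 0.35), Timp1 5.57-fold (2.48 ± 0.23) and the amino acid transporter gene Slc38a1 5.1-fold (2.35 ± 0.26). Prnd fell 12.1-fold (-3.60 ± 0.14), the carbonic anhydrase gene Car2 was at -3.41 and Prm1 fell 5.05-fold (-2.33 ± 0.31). All of these were beyond all 8 WT in 4 of 4 arrays. Prkar2b rose 2.37-fold (1.24 ± 0.11), and Prkar2a was at -2.31 ± 0.24. Cyp21a1 rose at least 3.53-fold (1.82 ± 0.26), Cyp11a1 1.95-fold (0.96 ± 0.13) and Hsd17b3, the enzyme that makes testosterone, 1.9-fold (0.92 ± 0.19), whereas Hsd3b6 fell 2.25-fold (-1.17 ± 0.28, adjusted p = 0.0036).

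By list in the arrays labelled srKO at 2 months, 16 of 19 spermatid genes fell (17 adjusted over the list alone), with adjusted p = 8.4e-15, but 0.13 with an estimated correlation. Of 17 macrophage genes 13 rose (16 adjusted over the list alone; adjusted p = 5.6e-08, and 0.29 with an estimated correlation). Among them were Lyz2 (1.32) and the antigen presentation gene H2-Aa (1.34). Of 7 interferon genes 5 rose (5 adjusted over the list alone; adjusted p = 0.0057, and 0.47 with an estimated correlation). Among them were Usp18 (0.82) and Oas2 (0.64). Of 21 matrix genes 10 rose (10 adjusted over the list alone; adjusted p = 0.00042, and 0.54 with an estimated correlation). Col4a1 (1.13) was among them. Of 9 endothelial genes 6 rose (7 adjusted over the list alone; adjusted p = 0.0036, and 0.53 with an estimated correlation). Kdr (1.08) was among them. Of 8 Leydig genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0036, and 0.47 with an estimated correlation). Sult1e1 (1.38) was among them. Of 9 steroidogenic genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.025, and 0.54 with an estimated correlation). This list was not called with the stricter filter (adjusted p = 0.061), the replicate block (adjusted p = 0.1) or WT replicates 1 to 4 alone (adjusted p = 0.12). Of 22 Sertoli cell genes 7 rose and 2 fell (9 and 3 adjusted over the list alone; adjusted p = 0.12), with Inha at 1.36 ± 0.12 and Fshr at -1.09 ± 0.12. Of 15 cholesterol genes 1 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.74), with Cyp51 at -0.87 and Fdps at -0.63. Of 22 meiotic genes 2 rose and 2 fell (1 and 2 adjusted over the list alone; 0 and 4 after centring, 5 and 4 after quantile normalization; adjusted p = 0.8).

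Not called in the arrays labelled srKO at 2 months were PKA (3 higher and 2 lower of 8, adjusted p = 0.86, mean -0.10 and median 0.12), cAMP and CREB targets (4 higher and 3 lower of 21, adjusted p = 0.74), adrenal (2 of 5 higher, adjusted p = 0.13), granulosa (3 higher and 1 lower of 15, adjusted p = 0.74; Wnt4 at 1.00), WNT (1 of 15 lower, adjusted p = 0.86), spermatogonia (2 of 18 lower, adjusted p = 0.27), myoid (3 higher and 1 lower of 7, adjusted p = 0.72; Acta2 at 0.45), lymphocytes and mast cells (1 of 6 lower, adjusted p = 0.72) and reference genes (3 of 8 higher, adjusted p = 0.19). The bone, cell cycle, epididymal and adipose lists had 0 members called (adjusted p of 0.86 or more). In all, 4837 genes were called, 2785 higher and 2052 lower, and 524 changed at least 2-fold (130 higher, 394 lower). After centring, 2208 were higher and 2309 lower. No alternative moved the count by more than 1.5 times.

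The arrays labelled lrKO at 2 months again had Sema7a among the largest rises, at 2.17-fold (1.12 ± 0.13, adjusted p = 0.00093), with the albumin gene Alb (1.12, adjusted p = 0.0011) and Xkr9 (1.03, adjusted p = 0.00095). Hsd17b3 fell 2.56-fold (-1.35 ± 0.19, adjusted p = 0.0017), and Cdca7l (-1.29) and Itih2 (-0.96) also fell. Each of these lay beyond all 8 WT in 4 of 4 arrays. Hsd3b6 fell 3.01-fold (-1.59 ± 0.28, adjusted p = 0.012) and Cyp21a1 rose at least 2.53-fold (1.34 ± 0.26, adjusted p = 0.034). Hsd3b6 was not called without lrKO replicate 2 (adjusted p = 0.078) or 3 (adjusted p = 0.077), with the replicate block (adjusted p = 0.083), with all 8 groups (adjusted p = 0.056) or against WT replicates 5 to 8 alone (adjusted p = 0.12). Cyp21a1 was not called with trend and robust eBayes (adjusted p = 0.06), the replicate block (adjusted p = 0.081) or WT replicates 5 to 8 alone (adjusted p = 0.11), nor without lrKO replicate 2 (adjusted p = 0.17) or 3 (adjusted p = 0.18) or any of WT replicates 1 to 7 (adjusted p = 0.05, 0.057, 0.056, 0.066, 0.065, 0.062 and 0.072).

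By list in the arrays labelled lrKO at 2 months, 1 of 15 cholesterol genes rose, Hsd17b7 (0.76, adjusted p = 0.0035), and 9 rose adjusted over the list alone (mean 0.28, adjusted p = 2e-11, but 0.088 with an estimated correlation). Dhcr7 (0.67, adjusted p = 0.081) and Msmo1 (0.58, adjusted p = 0.061) did not pass over all genes, although both did with array weights, only the groups compared or all 8 groups. Msmo1 also passed after quantile normalization or centring, and without WT replicate 3 (0.62, adjusted p = 0.04). Hsd17b7 was not called with the replicate block (0.64, adjusted p = 0.079). Of 9 steroidogenic genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.95, mean -0.15 and median 0.07). The cAMP (adjusted p = 0.014, 0 of 21 members called) and adrenal lists (adjusted p = 0.014, 1 of 5 members higher) were called higher and the cell cycle list lower (adjusted p = 0.028, 0 of 12 members called), but each had adjusted p = 0.42 with an estimated correlation and was not called with the replicate block. Of 22 Sertoli cell genes 1 fell, Cst9 (-0.51, adjusted p = 0.0091; adjusted p = 0.79 for the list), which was not called without lrKO replicate 3 (adjusted p = 0.052), with all 8 groups (adjusted p = 0.27), with the replicate block (adjusted p = 0.083) or against WT replicates 5 to 8 alone (adjusted p = 0.075). The other lists had 0 members called and adjusted p of 0.18 or more. In all, 35 genes were called, 21 higher and 14 lower, and 13 changed at least 2-fold (9 higher, 4 lower). The count was 260 against WT replicates 1 to 4 alone, 20 against WT replicates 5 to 8 alone, 54 with the replicate block, 145 with array weights, 83 with all 8 groups and 78 with only the groups compared. It was 16 without lrKO replicate 2 and 18 without lrKO replicate 3.

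**Figure D4:**
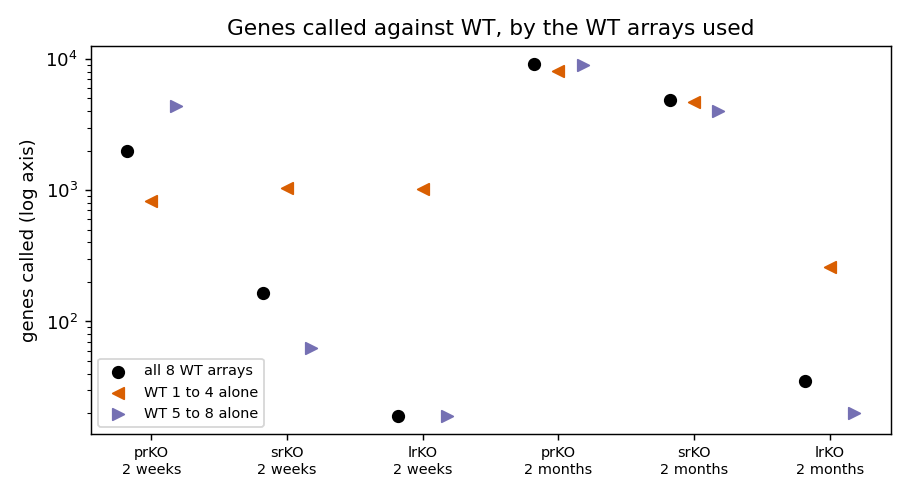
Genes called against WT (vertical axis, log scale) in each line and age (horizontal axis) with all 8 WT arrays, WT replicates 1 to 4 alone or WT replicates 5 to 8 alone. At 2 weeks the prKO counts were 1994, 830 and 4361.

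At 2 months 3823 genes were called in the same direction in prKO and srKO (2129 higher, 1694 lower) and 61 in opposite directions. Prnd, Serpina3n and Timp1 were shared. Independent lists would share 725 higher and 459.7 lower. Simulated unchanged groups shared 0 on average at both ages, which is no baseline for lists this long. The log2 changes correlated across genes with r = 0.74 (simulated mean 0.30), their covariance was 0.1571 (simulated 0.0056), and 3385 and 2943 genes were shared when each line was set against different WT arrays. At 2 weeks 54 were shared (51 higher, 3 lower) and 0 were opposite, against 11.8 and 0.4 for independent lists, with Pde7b and Prkar2b among them. Here r was 0.32 (simulated 0.23), the covariance was 0.0193 (simulated 0.0046), and with different WT arrays 34 and 66 genes were shared, with r of 0.33 and -0.17. At 2 weeks lrKO shared 1 gene with prKO (2 opposite) and 0 with srKO (0 opposite), with r of -0.32 and -0.27 (simulated 0.27 and 0.32; with different WT arrays 0.05 and -0.67 for prKO, -0.28 and -0.61 for srKO). At 2 months it shared 14 and 8 (8 and 7 opposite), with r of -0.13 and -0.14 (simulated 0.28 and 0.34; with different WT arrays -0.09 and -0.27, -0.30 and -0.19).

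At 2 weeks Cyp21a1 was at least 16.7-fold higher in prKO than in srKO (4.06 ± 0.26, adjusted p = 1.2e-08), Slc7a11 8.05-fold (3.01 ± 0.20) and the lipocalin gene Lcn2 7.62-fold (2.93 ± 0.46), each in 4 of 4 prKO arrays above all srKO. The Y RNA genes Rny1 (-1.74 ± 0.39, adjusted p = 0.0065) and Rny3 (-1.65 ± 0.33) were lower, as was the score of small RNA genes as a class (-0.36 in prKO, 0.22 in srKO). Prkar1a was 1.23-fold lower in prKO (-0.29 ± 0.08, adjusted p = 0.025), which was not called without prKO replicate 1 (adjusted p = 0.088) or 4 (adjusted p = 0.066) or srKO replicate 3 (adjusted p = 0.059) or 4 (adjusted p = 0.081), or with only the groups compared (adjusted p = 0.061). Of 9 steroidogenic genes 8 were higher in prKO (9 adjusted over the list alone; adjusted p = 7.2e-12, and 0.021 with an estimated correlation). Of 15 cholesterol genes 11 were higher (14 adjusted over the list alone; adjusted p = 2.5e-12), of 21 matrix genes 17 (18 adjusted over the list alone; adjusted p = 2.1e-15) and of 17 macrophage genes 9 (10 adjusted over the list alone; adjusted p = 1.4e-07), and these 3 lists each had adjusted p = 0.095 with an estimated correlation. In all, 2234 genes were called (1312 higher, 922 lower, 244 at least 2-fold), and after centring 1006 were higher and 1828 lower. The count was 3650 with array weights, 165 with prKO set against WT replicates 1 to 4 and srKO against 5 to 8, 4079 with the reverse, and 1415 without prKO replicate 4. The calls of Lcn2, Rny1 and Rny3 ended in the first crossed assignment (adjusted p = 0.18, 0.73 and 0.51).

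Against lrKO at 2 weeks, prKO had at least 18.3-fold higher Cyp21a1 (4.19 ± 0.26), 10.7-fold higher Pde7b (3.42 ± 0.23) and 9.57-fold higher Star (3.26 ± 0.27), in 4 of 4 arrays above all lrKO, with Nr4a1 2.34-fold higher (1.23 ± 0.15) and Prkar1a 1.77-fold lower (-0.82 ± 0.08, adjusted p = 2.1e-06). Of 9 steroidogenic genes 8 were higher (8 adjusted over the list alone; adjusted p = 3.7e-11, and 0.027 with an estimated correlation), and of 21 cAMP and CREB targets 9 (9 adjusted over the list alone; adjusted p = 7.2e-05, and 0.032 with an estimated correlation). In all, 3121 genes were called (1980 higher, 1141 lower, 351 at least 2-fold; 1685 higher and 1599 lower after centring). The count was 4911 with array weights, 274 and 5682 with the crossed WT assignments, and 1968, 1893 and 1728 without prKO replicate 1, prKO replicate 4 and lrKO replicate 4.

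In srKO against lrKO at 2 weeks, Pde7b was 4.77-fold (2.25 ± 0.23, adjusted p = 3.4e-05), Cst9 3.57-fold (1.84 ± 0.26), Pde10a 2.78-fold (1.48 ± 0.16) and Prkar2b 2.34-fold higher (1.23 ± 0.14), and Prkar1a was 1.44-fold lower (-0.53 ± 0.08, adjusted p = 0.0022), each beyond all lrKO in 4 of 4 arrays. Of 21 cAMP and CREB targets 2 were higher (6 adjusted over the list alone; adjusted p = 0.0053, but 0.28 with an estimated correlation). In all, 370 genes were called (293 higher, 77 lower, 29 at least 2-fold). The count was 2762 with array weights, 1027 with only the groups compared and 1153 with all 8 groups. It was 134, 121, 125 and 1015 without srKO replicate 1, 2, 3 and 4, and 181, 184, 180 and 96 without lrKO replicate 1, 2, 3 and 4.

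At 2 months prKO exceeded the arrays labelled srKO in Dpt (13-fold, 3.70 ± 0.34), Mmp2 (12.6-fold, 3.65 ± 0.38), Mrap (4.78-fold, 2.26 ± 0.22), Star (3.19-fold, 1.67 ± 0.27) and the isoprenoid enzyme gene Fdps (2.99-fold, 1.58 ± 0.13), in 3 of 3 arrays above all srKO. H2-Aa was 3.16-fold lower (-1.66 ± 0.25), Hsd3b6 3.93-fold lower (-1.98 ± 0.35) and Prkar1a 1.45-fold lower (-0.53 ± 0.10, adjusted p = 0.00093). Of 15 cholesterol genes 13 were higher (13 adjusted over the list alone; adjusted p = 4.1e-13, but 0.053 with an estimated correlation), of 21 matrix genes 19 were higher (20 adjusted over the list alone; adjusted p = 7.8e-13, but 0.17 with an estimated correlation), and of 22 meiotic genes 12 were lower (16 adjusted over the list alone; adjusted p = 9.5e-08, but 0.13 with an estimated correlation). Of 6 adipose genes 5 were higher (6 adjusted over the list alone; adjusted p = 0.00067, but 0.22 with an estimated correlation). In all, 4860 genes were called (2556 higher, 2304 lower, 341 at least 2-fold; 1865 higher and 3615 lower after centring). The count was 1083 with only the groups compared, 455 with prKO set against WT replicates 1 to 4 and srKO against 5 to 8, and 2683 without prKO replicate 3. In that crossed assignment Star (0.84, adjusted p = 0.067), H2-Aa (adjusted p = 0.054) and Prkar1a (adjusted p = 0.13) were not called.

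Against the arrays labelled lrKO at 2 months, prKO had 28.2-fold higher Dpt (4.82 ± 0.34), 21.4-fold higher Mmp2 (4.42 ± 0.38), 4.91-fold higher Lyz2 (2.29 ± 0.28) and 3.54-fold higher Star (1.82 ± 0.27), with Prnd 18.5-fold lower (-4.21 ± 0.17) and Tssk6 4.73-fold lower (-2.24 ± 0.24), in 3 of 3 arrays beyond all lrKO. Of 19 spermatid genes 18 were lower and 1 higher (18 and 1 adjusted over the list alone; adjusted p = 3.4e-08, but 0.23 with an estimated correlation). Of 6 adipose genes 6 were higher (6 adjusted over the list alone; adjusted p = 0.0092, but 0.36 with an estimated correlation), with scores of 3.03, 0.145 and 1.65 in prKO replicates 1, 2 and 3. In all, 8660 genes were called (4836 higher, 3824 lower, 1838 at least 2-fold; 3559 higher and 5533 lower after centring), and 5674 with prKO set against WT replicates 1 to 4 and lrKO against 5 to 8. In srKO against lrKO at 2 months, Timp1 was 6.07-fold (2.60 ± 0.26), Hsd17b3 4.85-fold (2.28 ± 0.22, adjusted p = 6.2e-07) and H2-Aa 2.77-fold higher (1.47 ± 0.24), and Prnd was 14.3-fold (-3.84 ± 0.16), Tssk6 5.36-fold (-2.42 ± 0.23) and Cyp51 2.09-fold lower (-1.06 ± 0.13), in 4 of 4 arrays beyond all lrKO. Of 19 spermatid genes 17 were lower (18 adjusted over the list alone; adjusted p = 1.8e-14, but 0.14 with an estimated correlation) and of 17 macrophage genes 13 higher (14 adjusted over the list alone; adjusted p = 1.1e-05, but 0.41 with an estimated correlation). In all, 5072 genes were called (2936 higher, 2136 lower, 705 at least 2-fold; 2134 higher and 2407 lower after centring).

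Non-additivity, the prKO change minus the srKO and lrKO changes, was at 2 weeks positive for Cyp21a1 (4.04 ± 0.34, adjusted p = 9e-07; near background in the other genotypes), Slc7a11 (3.31 ± 0.27) and Cyp11a1 (2.92 ± 0.27), and negative for Rny1 (-2.56 ± 0.52) and Rny3 (-2.52 ± 0.44). Of 9 steroidogenic genes 5 were positive (8 adjusted over the list alone; adjusted p = 1.1e-10, and 0.033 with an estimated correlation). In all, 1537 genes were called (984 positive, 553 negative, 331 at least 2-fold; 760 and 1020 after centring). The count was 3604 with WT replicates 1 to 4 alone, 694 with WT replicates 5 to 8 alone, 3031 with the replicate block, 24 and 4134 with the crossed WT assignments, and 946 without prKO replicate 4. The 24 did not include Rny1 (adjusted p = 0.93) or Rny3 (adjusted p = 0.79). At 2 months it was positive for Mmp2 (4.00 ± 0.49), Dpt (3.87 ± 0.44), Mrap (1.90 ± 0.28) and Nsdhl (1.27 ± 0.13) and negative for H2-Ab1 (-1.48 ± 0.24). In all, 3090 genes were called (1784 positive, 1306 negative, 407 at least 2-fold; 1269 and 2252 after centring), with 15 of 21 matrix genes positive (17 adjusted over the list alone; adjusted p = 1.2e-11, but 0.23 with an estimated correlation). The count was 1543 with WT replicates 5 to 8 alone, 4 with prKO set against WT replicates 1 to 4 and the other lines against 5 to 8, 1686 without prKO replicate 3 and 1993 without srKO replicate 3. In that crossed assignment Mmp2 (adjusted p = 0.11), Dpt (adjusted p = 0.1), Mrap (adjusted p = 0.18) and H2-Ab1 (adjusted p = 0.22) were not called.

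Between 2 weeks and 2 months in WT, genes of sperm formation rose most: the sperm mitochondrial capsule gene Smcp at least 249-fold (7.96 ± 0.08, adjusted p = 6.7e-40) and the transition protein gene Tnp2 185-fold (7.53 ± 0.20), in 8 of 8 arrays above all arrays of 2 weeks. Col1a1 fell 9.6-fold (-3.26 ± 0.17) and Dpt 10.2-fold (-3.35 ± 0.29). Of 19 spermatid genes 18 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 9.2e-16, and 0.0085 with an estimated correlation). Of 21 matrix genes 21 fell (21 adjusted over the list alone; adjusted p = 0.00011, but 0.93 with an estimated correlation), and of 22 Sertoli cell genes 20 fell (20 adjusted over the list alone; adjusted p = 9e-05, but 0.93 with an estimated correlation). In all, 15515 genes were called, 5070 higher and 10445 lower at 2 months, and 5882 changed at least 2-fold (2637 higher, 3245 lower).

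A line's change against WT differed between ages in 5351 genes for prKO (3011 with a higher and 2340 with a lower change at 2 months; 2176 and 3009 after centring). The change was lower at 2 months for Prnd (-3.58 ± 0.21), the cAMP-induced gene Nr4a1 (-1.73 ± 0.21) and Cyp11a1 (-1.04 ± 0.24) and higher for Ifi205 (3.68 ± 0.39). Spermatid genes had 16 of 19 lower (18 adjusted over the list alone, with 1 higher; adjusted p = 1.5e-10, but 0.062 with an estimated correlation). For srKO, 3278 genes did (1613 higher, 1665 lower; 1000 and 2047 after centring; 4975 with array weights), with a higher change for Serpina3n (3.20 ± 0.61), Timp1 (2.67 ± 0.28) and Cyp21a1 (1.66 ± 0.36) and a lower one for Prnd (-3.72 ± 0.20) and Prm1 (-2.36 ± 0.34). Of 17 macrophage genes 13 had a higher change at 2 months (17 adjusted over the list alone; adjusted p = 8.8e-12, and 0.034 with an estimated correlation), and of 19 spermatid genes 14 a lower one (16 adjusted over the list alone; adjusted p = 2.3e-15, and 0.0098 with an estimated correlation). Spermatid genes were low at 2 weeks (Prm1 mean 6.19 in WT, against 11.59 at 2 months), so their difference rests on the fall at 2 months. For lrKO, 19 genes did (10 higher, 9 lower), including Alb (1.15 ± 0.21, adjusted p = 0.0074) and the cholesterol exporter gene Abca1 (-0.88 ± 0.14, adjusted p = 0.0013). The lrKO count was 50 with array weights, 119 against WT replicates 1 to 4 alone, 12 and 11 without lrKO replicate 1 and 3 of 2 weeks, and 12 and 12 without lrKO replicate 2 and 3 of 2 months.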

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

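The tests of WT replicate sets, meiotic genes and Sema7a were chosen after the results were seen. Regroupings and checks for far arrays were planned. Chance alone sets about 1 in 20 groups apart in the check for far arrays. It found 16 of 161 pairs of gene list and group, and 29 of 380 pairs of gene and group.

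WT replicates 5 to 8 differed from 1 to 4 in 221 genes at 2 weeks (58 higher, 163 lower) and 407 at 2 months (155 higher, 252 lower), and 11.15% and 11.72% of genes had no overlap between the sets, where chance gives 2.86%. Small RNA genes, a class of 83, had a median 0.28 higher in replicates 5 to 8 at 2 weeks. Random gene sets (10000), which ignore spread between animals, gave -0.058 to 0.033. At 2 months the median was 0.012 (203 sets gave as much), but the mean score was lower (-0.03 against 0.03). A batch of RNA preparation or arrays is a candidate from 2 weeks only. Germ cell stage stays open. At 2 weeks 3 of 4 arrays of replicates 5 to 8 exceeded all of 1 to 4 in meiotic score, too few to decide. Litters of different lines, named in the design for WT, were not tested and stay open.

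Meiotic prophase genes varied among arrays of the same group at 2 weeks. Against loss of Prkar1a as the cause, WT arrays spanned -0.568 to 0.373 (SD 0.38) and 3 lay at or below the highest prKO array. A part in the lower prKO mean (-0.34, exact permutation p = 0.13) stays open. The SD of pachytene genes between WT arrays was 7.35 times larger at 2 weeks than at 2 months (median ratio), so the stage of the first wave of germ cells may differ among animals. A batch of RNA preparation or arrays cannot be told apart from this, since over the 8 WT arrays Spearman's rho with the small RNA score was 0.43 (exact permutation p = 0.3; Pearson's r 0.36, exact permutation p = 0.37; r 0.43 without the 2 farthest arrays), too few arrays to decide.

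Sema7a was higher in lrKO at both ages, with 2.14-fold at 2 weeks and 2.17-fold at 2 months in 4 of 4 arrays each. Loss of Prkar1a in steroidogenic cells as the whole cause is argued against at 2 weeks, where prKO, which also targets these cells, was lower than lrKO by a log2 difference of -1.30 (adjusted p = 1.4e-08). At 2 months that difference was -0.26 (adjusted p = 0.2) and Sema7a exceeded WT in prKO (0.85, adjusted p = 6.8e-05) but also in srKO (0.47, adjusted p = 0.01), whose Cre is not for steroidogenic cells, and Prkar1a was not called in lrKO (0.05 and 0.04 at the 2 ages), so what raised it then stays open. Sema7a lies 1 position from Cyp11a1 in the order of protein-coding genes, so an effect of the Cyp11a1:Cre allele on genes beside Cyp11a1 may contribute. The neighbour Ccdc33 was not called (0.85, adjusted p = 0.075 at 2 weeks; 0.51, adjusted p = 0.23 at 2 months), nor was Ubl7 (0.15 at each age).

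Other splits of the same arrays were counted for each number of called genes, the real split included. Chance was excluded for prKO against WT at 2 weeks (1 of 100 splits as large; 1994 real, 354 highest other) and at 2 months (1 of 100; 9206 and 3492), and for srKO at 2 months (1 of 100; 4837 and 823). For srKO at 2 weeks it was not excluded (5 of 100; 166 and 2793), and the highest split set WT replicates 2, 6, 7 and 8 apart. For lrKO it was left open (2 of 100 at each age). At 2 weeks counts were 19 and 1653, with WT replicates 1, 4 and 5 and lrKO replicate 2 apart. At 2 months they were 35 and 502, with exactly WT replicates 1 to 4 apart. Splits calling many times the real number point to a structure among WT arrays. At 2 weeks it followed the meiotic score. This was highest in WT replicates 2, 6, 7 and 8 (0.226 to 0.373) and lowest in 1, 4 and 5 (-0.568 to -0.287).

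Between lines 1 of 35 splits was as large in each case, so chance was excluded: at 2 weeks prKO against srKO gave 2234 (highest other 1), prKO against lrKO 3121 (1) and srKO against lrKO 370 (0), and at 2 months the values were 4860 (3120), 8660 (4781) and 5072 (0). Non-additivity splits (1537 and 1 at 2 weeks, 3090 and 5 at 2 months, 1 of 100 each) tested any genotype effect, not additivity. WT between ages had 1 of 100 (15515 and 14031). Splits for change with age tested any line effect, not its difference by age. The prKO line gave 1 of 100 (5351 and 1581), as did srKO (3278 and 2603). In lrKO (3 of 100, 19 and 463) a far higher split points to array structure.

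WT replicate 4 at 2 weeks stood above the other WT arrays in the mean log2 deviation of the cAMP (0.3, nearest 0.04), WNT (0.41, nearest 0.06), myoid (1.45, nearest 0.04) and matrix lists (0.75, nearest 0.06). At 2 months WT replicate 4 stood above in the cAMP (0.22, nearest 0.02) and myoid lists (0.42, nearest 0.06). Single arrays also stood apart for Leydig genes in lrKO at 2 weeks (replicate 3, 0.1, nearest -0.07), spermatogonial genes in lrKO at 2 weeks (replicate 1, -0.14, nearest -0.1) and srKO at 2 months (replicate 1, 0.09, nearest -0.13), and macrophage genes in prKO at 2 weeks (replicate 4, 0.42, nearest 0.21) and srKO at 2 months (replicate 2, 1.07, nearest 0.64). The same held for matrix genes in srKO at 2 weeks (replicate 4, -0.2, nearest 0.1), epididymal genes in lrKO at 2 months (replicate 4, 0.48, nearest -0.02), adipose genes in WT at 2 weeks (replicate 2, 0.93, nearest 0.04), and reference genes in lrKO at 2 weeks (replicate 2, 0.04, nearest 0) and srKO at 2 months (replicate 2, 0.32, nearest 0.13).

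Among named genes, WT replicate 4 at 2 weeks stood above the other WT arrays in log2 intensity for Nr4a3 (6.46, nearest 5.86), Lum (8.85, nearest 7.61), Mmp2 (10.2, nearest 9.49), Lox (8.98, nearest 7.8), Kdr (8.67, nearest 8.25), Cpa3 (6.44, nearest 5.09) and Col1a1 (12.16, nearest 11.45), and below for Ddost (11.53, nearest 11.87). Other WT arrays at 2 weeks stood apart for C7 (replicate 2, 8.49, nearest 7.05), Hsd3b1 (replicate 6, 7.64, nearest 8.04) and Nr4a1 (replicate 8, 8.34, nearest 7.81). At 2 weeks prKO arrays stood apart for Star (replicate 4, 11.78, nearest 11.24) and Tnni3 (replicate 2, 8.97, nearest 7.95), an srKO array for Tmem159 (replicate 3, 7.91, nearest 8.07), and lrKO arrays for Gabbr1 (replicate 4, 7.96, nearest 8.92), Cst9 (replicate 2, 11.24, nearest 9.47) and Slc7a11 (replicate 2, 5.49, nearest 4.72). WT arrays at 2 months stood apart for Serpina3n (replicate 1, 7.11, nearest 6.06), Cyp11b1 (replicate 1, 5.31, nearest 4.88), Col3a1 (replicate 7, 7.99, nearest 7.55), Lyz2 (replicate 4, 7.76, nearest 7.24), Acta2 (replicate 4, 10.21, nearest 9.91), Cd163 (replicate 8, 4.65, nearest 4.92), Itih2 (replicate 8, 6.58, nearest 6.98) and Gapdh (replicate 2, 10.62, nearest 10.85). At 2 months srKO arrays stood apart for Klk1b8 (replicate 3, 5.45, nearest 7.49), Nr5a1 (replicate 2, 8.37, nearest 7.84) and Star (replicate 2, 10.21, nearest 9.61), and an lrKO array for H2-Aa (replicate 1, 5.47, nearest 5.63).

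The change against WT differed between ages by limma's test in 5351 genes for prKO, 3278 for srKO and 19 for lrKO. In prKO the list means differed (2 months minus 2 weeks) for Sertoli (0.42, adjusted p = 0.00059), steroidogenic (-0.72, adjusted p = 0.048), Leydig (0.68, adjusted p = 0.0076), spermatid (-1.01, adjusted p = 1.5e-10), macrophage (0.51, adjusted p = 0.011), endothelial (0.67, adjusted p = 0.011), matrix (0.92, adjusted p = 2.5e-05), adipose (1.22, adjusted p = 0.046) and reference genes (0.44, adjusted p = 0.007). With an estimated correlation the adjusted p was 0.062 for spermatid genes, 0.08 for reference genes and 0.43 for the others. Genes of prKO that differed were Prkar1a (0.48), Cyp11a1 (-1.04), Nr5a1 (0.44), Prkar2b (1.35), Nr4a1 (-1.73), Inha (0.86), Mmp2 (2.42), Cd163 (0.61), Kdr (0.95), Cyp11b1 (1.77) and Sfrp1 (1.65). In srKO the lists were Leydig (0.6, adjusted p = 0.0057), spermatid (-1.1, adjusted p = 2.3e-15), macrophage (0.95, adjusted p = 8.8e-12), endothelial (0.49, adjusted p = 0.018), matrix (0.46, adjusted p = 0.001) and interferon (0.56, adjusted p = 0.0014), with 0.49, 0.0098, 0.034, 0.64, 0.65 and 0.25 for an estimated correlation, and the genes were Prkar1a (0.72), Prkar2b (0.46), Inha (0.92) and Cyp21a1 (1.66). In lrKO the lists were cAMP (0.17, adjusted p = 0.0037), cholesterol (0.4, adjusted p = 5.9e-12), granulosa (0.15, adjusted p = 0.017) and meiotic genes (-0.28, adjusted p = 0.0054), with 0.24, 0.15, 0.32 and 0.63 for an estimated correlation, and Cst9 differed by 1.17 (adjusted p = 0.046).

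Probe sets without a gene symbol, 13417 of them past the filter, lie outside the gene tests and were tested in the same way. At 2 weeks 147 were called in prKO (110 higher, 37 lower), 16 in srKO (16 higher) and 29 in lrKO (10 higher, 19 lower) against WT. At 2 months 2724 were called in prKO (1413 higher, 1311 lower), 879 in srKO (470 higher, 409 lower) and 34 in lrKO (28 higher, 6 lower).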

How the results depend on the processing

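The fits with WT replicates 1 to 4 or 5 to 8 alone, the crossed assignments of these WT arrays and the fit without the arrays high in Adam7 were chosen after the data were seen. Among the 18 counts of called genes, 183 values under other settings stayed within 1.5 times the reported count and 45 did not, and for counts that also required 2-fold the numbers were 190 and 38. Leaving out 1 array kept 205 counts within 1.5 times and moved 38. Of the tests of named genes under other settings, 3402 kept their direction and side of the threshold, 158 no longer passed, 26 newly passed and 1 reversed. Without 1 array the numbers were 3174, 248, 12 and 0. Of the list tests, 1940 stayed on their side, 84 no longer passed, 45 newly passed and 1 reversed. The reversed results were Kcnma1 in srKO against WT at 2 weeks, at -0.527 (adjusted p = 0.54) with the average of its probe sets, and the meiotic prophase list in lrKO against WT at 2 weeks, with adjusted p = 0.57 against WT replicates 5 to 8 alone. For Kcnma1 the cause was not tested.

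Centring moved the count of srKO against WT at 2 weeks to 276. Array weights gave, at 2 weeks, 3834 for prKO, 2234 for srKO and 37 for lrKO against WT, 3650 for prKO against srKO, 4911 for prKO against lrKO and 2762 for srKO against lrKO. They gave 145 for lrKO against WT at 2 months, and 4975 and 50 for the change with age in srKO and lrKO. Fitting only the groups compared gave 1241, 39 and 3 for prKO, srKO and lrKO against WT at 2 weeks, 1027 for srKO against lrKO at 2 weeks, 78 for lrKO against WT at 2 months and 1083 for prKO against srKO at 2 months. Fitting all 8 groups gave 265 for srKO and 38 for lrKO against WT at 2 weeks, 1153 for srKO against lrKO at 2 weeks and 83 for lrKO against WT at 2 months. For these 4 settings the cause was not tested. The non-additivity contrasts use all 4 genotypes, so they have no value with only the groups compared, and the comparisons between ages none with all 8 groups, which they already use.

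The replicate block gave 598, 595 and 583 for prKO, srKO and lrKO against WT at 2 weeks, 3031 for non-additivity at 2 weeks and 54 for lrKO against WT at 2 months. The lines have no replicates 5 to 8, so the block compares them with WT replicates 1 to 4 only. In 0 of 13 pairs of groups did every pair of arrays with the same number correlate by more than 0.1, which does not rule out pairing.

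WT replicates 1 to 4 alone gave 830, 1040 and 1026 for prKO, srKO and lrKO at 2 weeks, 3604 for non-additivity at 2 weeks, 260 for lrKO at 2 months and 119 for the change of lrKO with age. WT replicates 5 to 8 alone gave 4361 for prKO and 63 for srKO at 2 weeks, 694 for non-additivity at 2 weeks, 20 for lrKO at 2 months and 1543 for non-additivity at 2 months. With prKO set against WT replicates 1 to 4 and the other lines against 5 to 8, prKO against srKO gave 165 at 2 weeks and 455 at 2 months, prKO against lrKO 274 and 5674, and non-additivity 24 and 4. With the reverse assignment the values that moved were 4079, 5682 and 4134, all at 2 weeks. These settings differ in the WT arrays used.

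Overlaps restricted to 2-fold changes fell to 2 for prKO and srKO and 0 for prKO and lrKO at 2 weeks, and to 445 for prKO and srKO, 4 for prKO and lrKO and 3 for srKO and lrKO at 2 months, because fewer genes meet that criterion. With WT replicates 1 to 4 for the first-named line and 5 to 8 for the other, the overlap was 34 for prKO and srKO at 2 weeks, and at 2 months 7 for prKO and lrKO and 3 for srKO and lrKO. With the sets exchanged it was 8 for prKO and lrKO at 2 weeks and 18 for srKO and lrKO at 2 months.

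Leaving out 1 array gave, against WT at 2 weeks, counts from 1298 (without prKO replicate 1) to 3119 (without WT replicate 4) for prKO, 33 (srKO replicate 1) to 362 (srKO replicate 4) for srKO and 5 (lrKO replicate 3) to 23 (WT replicate 5) for lrKO. At 2 months the counts went from 7359 (prKO replicate 3) to 9288 (WT replicate 1) for prKO, 3514 (srKO replicate 2) to 4786 (WT replicate 8) for srKO and 16 (lrKO replicate 2) to 38 (WT replicate 8) for lrKO. Between lines at 2 weeks they went from 1415 (prKO replicate 4) to 1858 (srKO replicate 4) for prKO against srKO, 1728 (lrKO replicate 4) to 2661 (prKO replicate 3) for prKO against lrKO and 96 (lrKO replicate 4) to 1015 (srKO replicate 4) for srKO against lrKO. At 2 months the ranges were 2683 (prKO replicate 3) to 5253 (prKO replicate 1), 7309 (prKO replicate 3) to 8596 (prKO replicate 2) and 3814 (srKO replicate 2) to 4978 (srKO replicate 3). Non-additivity went from 946 (prKO replicate 4) to 1774 (WT replicate 8) at 2 weeks and from 1686 (prKO replicate 3) to 3929 (prKO replicate 1) at 2 months. The WT comparison between ages went from 15221 (WT replicate 1 of 2 weeks) to 15615 (WT replicate 1 of 2 months). The change with age went from 4503 (prKO replicate 3 of 2 months) to 5539 (prKO replicate 1 of 2 months) for prKO, 2447 (srKO replicate 2 of 2 months) to 3527 (WT replicate 4 of 2 weeks) for srKO and 11 (lrKO replicate 3 of 2 weeks) to 20 (WT replicate 8 of 2 months) for lrKO. The cause was not tested where a count rose without an array. The filter left out genes with every group mean at background, and small changes were limited by the number of arrays.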

Other observations

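The values given here were computed and chosen after the data were seen. Non-additivity of prKO at 2 weeks was called with every choice of WT arrays tried in 23 genes, among them the steroid genes Cyp21a1 (4.04), Cyp11a1 (2.92) and Hsd3b1 (2.21), the cystine transporter gene Slc7a11 (3.31), Adgrg7 (2.80), Ly6d (2.70), the lipopolysaccharide-binding protein gene Lbp (2.39), the antioxidant enzyme gene Pon3 (2.37) and the xanthine dehydrogenase gene Xdh (2.35). Over these genes, Sema7a apart, the log2 change was 0.25 to 4.22 in prKO, -0.50 to 0.40 in srKO and -0.51 to 0.10 in lrKO. Sema7a was the member with a negative value (-1.40). At 2 months 3 genes were called with every choice, Il33, which codes for an alarm cytokine (2.63), the cholesterol enzyme gene Nsdhl (1.27) and Rnase2a (1.98).

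In prKO replicate 1 at 2 months Adam7 was at 11.7 while the epididymal genes Lcn5, Lcn8 and Spag11b differed from the mean of the other prKO arrays by 0.22, -0.39 and 0.14. The mean small RNA score at 2 weeks was -0.18 in WT replicates 1 to 4, 0.18 in WT replicates 5 to 8, -0.36 in prKO, 0.22 in srKO and 0.27 in lrKO; at 2 months it was 0.03, -0.03, 0.48, 0.17 and -0.20.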
